A study of Homo sapiens with 16 samples.

How the data were processed

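Total RNA from the breast cancer cell lines HCC70 and MDA-MB-468 was profiled on Affymetrix Human Gene 1.0 ST arrays, which hold probes along the length of each transcript. There were 16 arrays in 8 groups of 2. Per the labels' protocols, cells were infected with viral supernatant of each vector, kept under puromycin selection and seeded at equal confluence a day before RNA extraction. The RNA was converted to cDNA and labelled with biotin.

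The deposited values are log2 signals, 1 per transcript cluster and array. Per the submitters' processing notes they were made with RMA in Affymetrix Expression Console. RMA corrects the background, normalizes between arrays and summarises the probes of a cluster on the log2 scale, so a log2 difference between arrays is a log ratio of signals and tends to be smaller than the true change for dim clusters. The software versions, and the genome build behind the cluster definitions, are not given in the sources used here, and no genome coordinates are reported. No scan date was among the values used, so batches could not be tested. Over all 33297 clusters the array medians ran from 5.37 to 5.53 and the values from 2.20 to 14.01. Between 43.1% and 44.5% of clusters reached a log2 signal of 6. An array gives no read depth; the number of arrays limits the precision.

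Groups came from the sample titles and descriptions. The series design gives each of the 4 treatments its own control, and 2 sets of HCC70 arrays with scrambled shRNA, called a and b in the titles, serve the EZH2 and the EED knockdown. Which set belongs to which knockdown is not stated outright. Set a was taken for EZH2 and set b for EED because the sample codes run in blocks that each hold 1 control pair and 1 treated pair; the reverse assignment and both sets together were run as alternatives. On the arrays, the difference between the shEZH2 and shEED groups correlated with the difference between sets a and b (r = 0.568 across clusters, which are not independent replicates). The labels name the control of the overexpression arrays as the plKO Puro vector and the treated arrays as fip EZH2; whether both constructs share a backbone is not given in the sources used here. Nothing says whether duplicates came from separate cultures. The error behind each p-value is the spread between duplicates, which may be technical and may leave out variation between cultures. By limma at an adjusted p under 0.05, sets a and b differed in 3677 clusters, more than any treatment differed from the control assigned to it. MDA-MB-468 had only 1 control pair, so control groups could not be compared there. Duplicates correlated at r = 0.986 to 0.997 over all clusters, and no pair held identical values.

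Gene symbols came from the platform annotation supplied with the values. Of all clusters, 19460 had exactly 1 symbol, 1754 had several and 12083 had none; 19429 of those with 1 symbol were found by Entrez identifier in a RefSeq gene table (GRCh38.p14), used for names only, and 0 symbols needed updating. Only clusters with exactly 1 symbol were named. A gene with several clusters was represented by the one with the highest mean over the 16 arrays. KRT18 had 2 clusters and was represented by cluster 8154725. The genome position of that cluster was not checked, so signal from a related sequence was not excluded. The 1-symbol rule leaves KRT17 and TP63 unnamed, and ELF5 and ESR1 stayed below the floor.

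Clusters were tested when at least 2 of the 16 arrays reached log2 6, which kept 16175 and left out 17122. Of those tested, 11712 had 1 symbol, 999 several and 3464 none, and 236 repeated the 16 values of another cluster. A linear model of 8 group means was fitted to all 16 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, giving 8 residual and 3.70 prior degrees of freedom. Each treatment was contrasted with its control, two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison; a cluster was called at an adjusted p under 0.05. Errors of log2 changes are standard errors from this fit. Differences between comparisons were tested as contrasts of the same model. Correlations of log2 changes are Pearson's r across tested clusters and are descriptive. Overlaps of calls are set beside the count for independent lists. All comparisons share the same error estimate for a cluster, so their calls are not independent and that count is not a chance level.

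The 18 gene lists were fixed before the data were examined, as were the comparisons, the other settings tried (except those said to be chosen later) and the rule for naming genes. They cover PRC2 and PRC1 subunits, mature luminal, luminal progenitor, basal and myoepithelial, and mesenchymal markers, epithelial junction genes, genes described as Polycomb targets in cancer cells, HOX genes, cell cycle genes, interferon response genes, antigen presentation genes, inflammatory cytokines and NF-kB targets, p53 targets and growth arrest, hypoxia and glycolysis, cholesterol synthesis, the unfolded protein and amino acid response, and markers of blood, fibroblast and endothelial cells. On the arrays, 347 of their genes were tested. Lists were tested against all other genes with camera from limma, with a preset inter-gene correlation of 0.01 and 1 cluster per gene, and adjusted over the lists within a comparison. The same test with an estimated correlation was an alternative. Another was fry, which asks whether the genes of a list moved one way against no change and does not compare them with other genes. Named genes are EZH2 and EED, a fixed panel of lineage genes (GATA3, KRT5, KRT14, KRT17, KRT8, KRT18, KIT, ELF5, ALDH1A3, TP63, EGFR, ESR1 and CDKN2A), genes from the 10 largest called rises and 10 largest called falls with both treated arrays on the same side of both controls, up to 4 called members of each list with the smallest adjusted p, or up to 2 with the smallest p where none was called, up to 10 genes called in both of a pair of comparisons, and the 5 largest differences each way between comparisons.

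The fit was tested on simulated data made from the EZH2 knockdown groups in HCC70. Of the clusters seeded with a log2 change of 0.5, 37 of 67 were recovered; 66 of 67 were recovered at 1 and 66 of 66 at 2, with 3 false calls among 172. With no change seeded, limma called 0 clusters and 0 lists in each of the 4 comparisons. The noise held no differences between cultures and no correlation between genes, so these figures do not give the rate of false calls in the measured data. The alternatives were no filter or a floor of log2 7, quantile normalization once more, centring each array on its median, leaving out each array in turn, the replicate number as a block, only clusters with 1 symbol, the other scrambled set or both, a mean-variance trend, a robust prior, array weights, a threshold of 0.01, a 2-fold minimum, and the 4 arrays of a comparison alone. Neither scaling moved the median change of all tested clusters by more than 0.1 on the log2 scale. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 (pandas 2.3.3, numpy 2.4.6).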

Results

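Gene expression was measured in HCC70 and MDA-MB-468, established human breast cancer lines of the basal-like type. The title of the series asks what EZH2 contributes to a mixed lineage identity in such cells. EZH2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which represses genes by methylating histones, and EED is a core subunit of the same complex. In HCC70, EZH2 was knocked down or overexpressed from cDNA and EED was knocked down. In MDA-MB-468, EZH2 was knocked down. Each of the 4 treatments had its own control, and each of the 8 groups was measured on 2 arrays. Log2 signals were RMA values, with array medians from 5.37 to 5.53 and 43.1% to 44.5% of clusters at log2 6 or above. Changes are treated minus control in log2 units with the standard error from limma (n = 2 arrays per group). Adjusted p-values are from limma with the Benjamini-Hochberg adjustment. Their error is the spread between duplicates, which may leave out variation between cultures. A called rise or fall is thus a difference between these samples and is not by itself shown to come from the treatment. Signal below a floor of log2 6 was not shown to be above background. Where a group mean lies below it, the change may be understated and its size and rank are uncertain.

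Against scrambled set a, EZH2 knockdown in HCC70 lowered EZH2 and KIT and raised interferon response genes. EZH2 itself (cluster 8143663) fell from 10.01 ± 0.01 (SD, n = 2) in scrambled set a to 8.54 ± 0.06 in the shEZH2 arrays. The change was -1.47 ± 0.07, 2.76-fold lower (adjusted p = 3.35e-07). EED (cluster 7942914) changed by -0.115 (adjusted p = 0.532). KIT, a receptor tyrosine kinase of luminal progenitors, fell by 1.74 ± 0.13 on the log2 scale (adjusted p = 6.78e-06) to a mean of 4.575, below the floor, so the fall may be larger. The basal keratin gene KRT14 fell by 0.82 ± 0.09 (adjusted p = 0.000122). The luminal regulator GATA3 changed by 0.21 (adjusted p = 0.388), KRT8 by 0.18 (0.246), KRT18 by 0.32 (0.0517) and KRT5 by -0.245 (0.0568), none of them past the threshold. EGFR at -0.08 (0.705), CDKN2A at -0.015 (0.927) and ALDH1A3 at 0.02 (0.912) were not past it either, and another ALDH1A3 cluster had the opposite sign. KRT18 (cluster 8154725, 1 of 2 with its symbol) passed the threshold without shEZH2 replicate 1 (0.43). It also passed with a floor of log2 7 (adjusted p = 0.0411), with 1-symbol clusters only (0.0372) and with both scrambled sets (0.0332). KRT5 passed it with a floor of log2 7 (0.0444) and after quantile normalization (0.039). ALDH1A3 passed it with a change below 0 against set b (-0.94, adjusted p = 3.23e-06) and with both sets (-0.462, 0.000362). Falls included the phospholipase gene PLA2G2A (-4.16 ± 0.12, adjusted p = 4.38e-09) and the calcium-binding protein gene CALB1 (-3.68 ± 0.10, adjusted p = 2.7e-09). KRT4 (-2.36), AKR1C2 (-2.60) and the matrix protease gene MMP7 (-2.32) also fell. The shEZH2 means of PLA2G2A (5.68), CALB1 (5.64) and AKR1C2 (5.14) were below the floor. Rises included the lactotransferrin gene LTF (2.57 ± 0.23), the ion channel gene TRPA1 (2.54 ± 0.15), the complement gene C1S (2.46 ± 0.15) and the fibronectin gene FN1 (2.06 ± 0.15), with TRPA1 below the floor in set a (4.05).

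Of 35 interferon response genes tested, 29 rose, 1 fell and 5 did not pass the test. Adjusted over the list alone, 31 rose and 1 fell. The antiviral genes IFIT1 (1.87 ± 0.14, 3.66-fold), MX2 (1.68) and MX1 (1.49 ± 0.10) were among them. The list shifted up against all other genes (camera adjusted p = 2.66e-25, and adjusted p = 0.0127 with an estimated correlation). Among 14 antigen presentation genes 5 rose and 0 fell (8 and 0 adjusted over the list alone). The list shifted up, with the class II genes HLA-DPA1 at 2.105 ± 0.19 and HLA-DPB1 at 1.59 (camera adjusted p = 0.00285, and adjusted p = 0.191 with an estimated correlation). Cholesterol synthesis genes shifted down, with 0 of 19 higher and 5 lower (0 and 11 adjusted over the list alone). Among them were DHCR7 at -0.45 ± 0.09 and TM7SF2 at -0.52 (camera adjusted p = 9.65e-05, and adjusted p = 0.191 with an estimated correlation). Of 16 luminal progenitor markers 1 rose and 5 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.0324, and adjusted p = 0.191 with an estimated correlation). The stem cell surface marker gene PROM1 (-1.23 ± 0.09) and KRT15 (-0.62) fell. Of 18 basal and myoepithelial markers 2 rose and 6 fell (4 and 8 adjusted over the list alone, camera adjusted p = 0.00321, and adjusted p = 0.0575 with an estimated correlation). The desmosome gene DSG3 was lower (-1.05 ± 0.14) and the contractile gene MYLK higher (1.01). Mesenchymal markers had 8 of 16 higher and 2 lower (8 and 3 adjusted over the list alone, camera adjusted p = 0.0237, and adjusted p = 0.191 with an estimated correlation). The vimentin gene VIM rose by 1.24 ± 0.09 and SNAI1 by 0.96. Of 26 cytokine and NF-kB target genes 7 rose and 2 fell (10 and 4 adjusted over the list alone, camera adjusted p = 0.0402, and adjusted p = 0.345 with an estimated correlation). S100A8 rose by 1.70 ± 0.13 and the chemokine gene CCL2 by 1.70. In set a MX2, HLA-DPA1 and HLA-DPB1 were below the floor.

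The other 11 lists were not past the threshold (camera adjusted p from 0.0818 to 0.839). Genes described as Polycomb targets went both ways, with 4 of 19 higher and 3 lower (5 and 3 adjusted over the list alone, camera adjusted p = 0.446). SFRP2 rose by 1.36 from below the floor and the receptor gene BMPR1B fell by 0.76 to below it. None of 40 cell cycle genes was called (0 higher and 0 lower, also adjusted over the list alone, camera adjusted p = 0.839). Mature luminal markers had 0 of 15 higher and 2 lower (2 and 4 adjusted over the list alone, camera adjusted p = 0.488). Given in the same order, epithelial junction genes had 0 of 23 and 3 (0 and 3, 0.0818), and HOX genes 0 of 12 and 2 (1 and 2, 0.446). Hypoxia and glycolysis genes had 5 of 26 and 1 (7 and 2, 0.15) and p53 targets 3 of 21 and 2 (4 and 2, 0.447). PRC2 subunits had 0 of 12 and 1 (1 and 1, 0.274) and PRC1 subunits 1 of 15 and 1 (1 and 1, 0.839). The unfolded protein and amino acid response had 1 of 26 and 0 (1 and 0, 0.446). Of the markers of other cell types 3 were tested and 0 were called (1 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.265). The mean, median and test did not all have the same sign for PRC1 subunits, mature luminal markers and cell cycle genes.

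In all, 1837 of 16175 clusters passed the threshold, 1181 higher and 656 lower, of which 128 and 53 changed at least 2-fold. The count was 767 without set a replicate 1, 688 without set a replicate 2 and 276 from the 4 arrays alone. Without shEZH2 replicate 2 the luminal progenitor (camera adjusted p = 0.109), mesenchymal (0.064) and NF-kB (0.218) lists were no longer past the threshold. Without set a replicate 1 the NF-kB list, DHCR7 (then -0.386) and TM7SF2 (then -0.489) were not. Against set b, with the same shEZH2 arrays and so not independently, 1018 of the 1837 calls were made again in the same direction and 81 in the opposite one. Interferon genes had 17 of 35 higher and 1 lower (camera adjusted p = 1.12e-05). KRT14 changed by -0.078 (adjusted p = 0.535), FN1 by 0.175 (0.414), KRT15 by -0.168 (0.116), MX1 by 0.27 (0.0578), LTF by -0.02, VIM by -0.17 and CCL2 by -0.225. The NF-kB list shifted down (camera adjusted p = 5.12e-05), and the basal (0.664) and mesenchymal (0.506) lists were not past the threshold. The luminal progenitor (4.52e-07), cholesterol (1.45e-08) and antigen presentation (0.0131) lists were past it in the same direction, and so was the epithelial junction list, shifted down (0.00328). EZH2, KIT, PLA2G2A, C1S and TRPA1 were past the threshold in the same direction with changes within 1.5 times. Of 44 named genes called against set a, 26 moved by over 1.5 times or changed sign. CALB1 was at -1.32, IFIT1 at 0.735, MX2 at 0.67, HLA-DPA1 at 1.26, HLA-DPB1 at 0.74, DSG3 at -0.53, SNAI1 at 0.63, SFRP2 at 0.52 and BMPR1B at -0.48. PROM1 (-2.12), DHCR7 (-0.95) and TM7SF2 (-0.96) fell further.

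**Figure D1:**
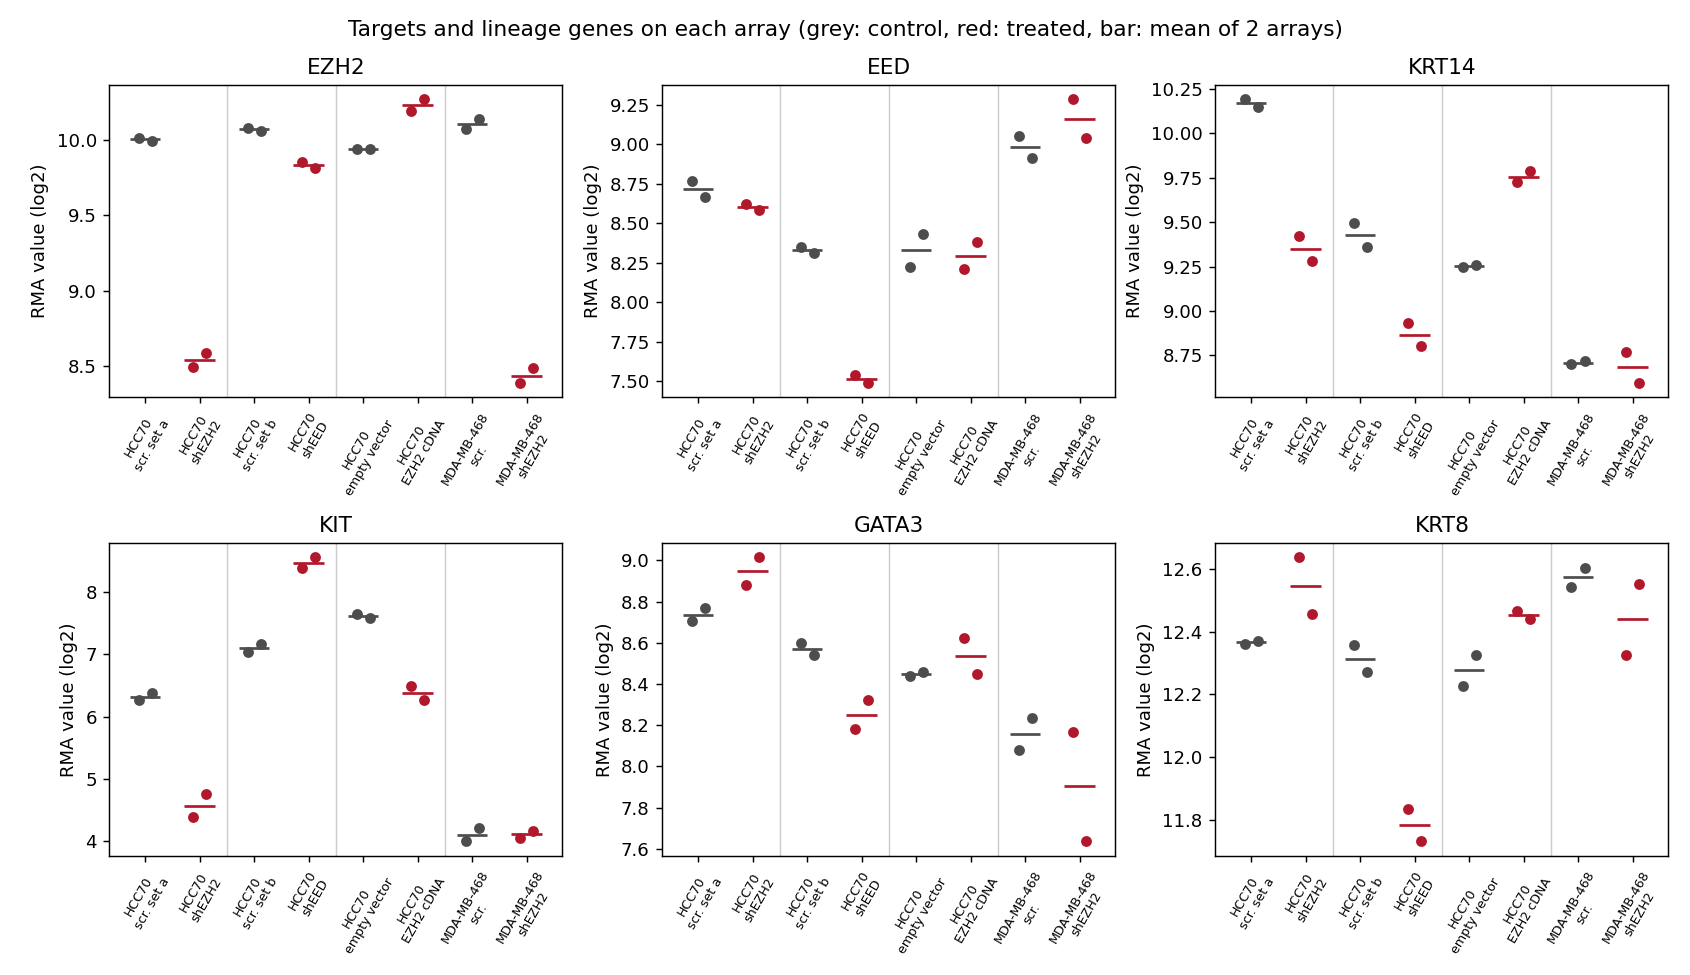
Log2 RMA signal (vertical axis) of EZH2, EED, KRT14, KIT, GATA3 and KRT8 on each array, with control arrays in grey, treated arrays in red and a bar at the mean of each pair. EZH2 was lower with shEZH2 in both lines, and KIT on the HCC70 arrays lay between 4.40 and 4.75 with shEZH2, between 8.37 and 8.55 with shEED and between 6.26 and 7.64 on the 6 control arrays.

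EZH2 knockdown in MDA-MB-468 lowered the growth factor binding protein gene IGFBP5. EZH2 fell by 1.675 ± 0.07 on the log2 scale, 3.19-fold (adjusted p = 2.56e-07), and EED changed by 0.18 (adjusted p = 0.313). IGFBP5 (-2.80 ± 0.10, adjusted p = 5.07e-08) and PLA2G2A (-1.56 ± 0.12) fell to means below the floor (4.95 and 5.52). FN1 (-1.37 ± 0.15, adjusted p = 0.000439), the matrix protease inhibitor gene TIMP3 (-1.45 ± 0.12) and CRISP3 (-1.46) also fell. Rises were called in ANTXR2 (1.61 ± 0.14), DSE (1.61 ± 0.09), the acute phase gene SAA1 (1.46 ± 0.14), the MAP kinase phosphatase gene DUSP6 (1.315), GDA (1.275) and the transcription factor gene ETV1 (1.25). ANTXR2 and ETV1 were below the floor in both groups and GDA in the control. In the lineage panel GATA3 (-0.25, adjusted p = 0.287), KRT5 (0.02, 0.899), KRT14 (-0.03, 0.883), KRT8 (-0.13, 0.394), KRT18 (-0.09, 0.591), ALDH1A3 (-0.19, 0.11), EGFR (-0.02, 0.948) and CDKN2A (-0.11, 0.398) were not past the threshold, though GATA3 was at -0.52 (adjusted p = 0.0337) without shEZH2 replicate 1. KIT was near the low end of the signal range in both groups (4.11 and 4.10).

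Of 40 cell cycle genes 0 rose and 10 fell (0 and 15 adjusted over the list alone). Among them were the mitotic kinase genes BUB1 at -0.57 ± 0.08 (adjusted p = 0.00198) and PLK1 at -0.385 (0.00925) and the replication gene MCM6 at -0.58 (0.00483). The list shifted down (camera adjusted p = 0.0186), but not with an estimated correlation (adjusted p = 0.311) or without shEZH2 replicate 2 (camera adjusted p = 0.0846). No other list was past the threshold (camera adjusted p from 0.0509 to 0.755). PRC2 subunits had 0 of 12 higher and 4 lower, the targeted EZH2 among them (0 and 6 adjusted over the list alone, camera adjusted p = 0.0509). In the same order, epithelial junction genes had 0 of 23 and 4 (0 and 10, 0.0509), with the desmocollin gene DSC2 at -0.955 ± 0.07. Antigen presentation genes had 1 of 14 and 0 (0 and 0, 0.0509) and NF-kB targets 2 of 26 and 1 (3 and 3, 0.0509). Interferon response genes had 2 of 35 higher and 6 lower (5 and 8 adjusted over the list alone, camera adjusted p = 0.682), among them XAF1 at -0.755 ± 0.11. Luminal progenitor markers had 0 of 16 higher and 4 lower (1 and 7 adjusted over the list alone, 0.184), including BBOX1 (-1.13 ± 0.09) and PROM1 (-0.65). Basal and myoepithelial markers had 0 of 18 and 4 (0 and 6, 0.202). Mesenchymal markers had 2 of 16 higher and 2 lower (2 and 3 adjusted over the list alone, 0.709), with VIM higher (0.90 ± 0.09). XAF1 was below the floor in both groups and BBOX1 in the shEZH2 arrays. Polycomb targets had 0 of 19 and 4 (0 and 4 adjusted over the list alone, 0.529) and hypoxia genes 0 of 26 and 5 (0 and 7, 0.542). For p53 targets the counts were 1 of 21 and 0 (1 and 0, 0.184), and for mature luminal markers 1 of 15 and 1 (1 and 1, 0.682). PRC1 subunits had 0 of 15 and 1 (1 and 3, 0.682) and markers of other cell types 0 of 3 and 1 (0 and 1, 0.529). HOX genes (0.184), cholesterol synthesis (0.216) and the unfolded protein and amino acid response (0.755) had no called member, also adjusted over each list alone. The median, mean and test differed in sign for mesenchymal markers and the unfolded protein response.

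In all, 1343 clusters passed the threshold, 442 higher and 901 lower, and 19 and 32 of them changed at least 2-fold. The share of higher calls was 32.9%, 18.8% (226 of 1200) when each array was centred on its median and 42.2% (480 of 1137) after quantile normalization once more. The count was 231 without scrambled replicate 2, 628 without shEZH2 replicate 1 and 21 from the 4 arrays alone. Without scrambled replicate 2 the calls of MCM6 (then -0.484) and PLK1 (then -0.406) ended.

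The effect of EZH2 knockdown differed between the lines in 2141 clusters by the limma interaction contrast, 1451 with a higher change in HCC70 and 690 with a lower one. EZH2 fell by similar amounts, with a difference of 0.21 ± 0.10 (HCC70 minus MDA-MB-468; adjusted p = 0.189). Against set a the interferon list differed, with 22 of 35 genes changing more upward in HCC70 and 0 downward (30 and 1 adjusted over the list alone, camera adjusted p = 8.58e-17, and adjusted p = 0.0458 with an estimated correlation). The camera adjusted p of every other list was then 0.124 or higher. KIT (-1.75 ± 0.18, adjusted p = 0.000188) and KRT14 (-0.79 ± 0.12, adjusted p = 0.00251) fell further in HCC70, but KIT lay below the floor in both MDA-MB-468 groups, so a fall there could not show. The difference for GATA3 was 0.46 (adjusted p = 0.148). Of the clusters called in both lines, 147 changed the same way (63 higher, against 32.3 for independent lists, and 84 lower, against 36.5). Another 147 went opposite ways, FN1 among them (119 higher in HCC70 and lower in MDA-MB-468, against 65.8, and 28 the reverse, against 17.9). These overlaps lay above the counts for independent lists whichever the direction. The changes correlated at r = -0.127 across clusters (-0.161 to -0.058 leaving out 1 array, and -0.025 with 1-symbol clusters only). PLA2G2A, the phosphate transporter gene SLC34A2 (-1.54 and -1.21) and VSNL1 (-1.10 and -1.15) fell in both lines. The protease inhibitor gene SERPINE2 (1.31 and 1.20), ETV1 (1.73 and 1.25) and SLCO2A1 (2.15 and 0.91) rose in both. The SLCO2A1 call in MDA-MB-468 ended without scrambled replicate 2 (then 0.896). ETV1 was below the floor in both groups of both lines, and SLCO2A1 in set a. The count of differing clusters was 1201 without set a replicate 1, 933 without set a replicate 2 and 921 without the MDA-MB-468 scrambled replicate 2. Against set b, the KRT14 difference was -0.05 (adjusted p = 0.823), the interferon list differed (camera adjusted p = 3.57e-05) and r was 0.104 (0.005 with both sets). The cholesterol (2.33e-07), NF-kB (4.38e-07) and luminal progenitor (1.73e-05) lists then changed more downward in HCC70, and the 3 markers of other cell types more upward (0.0319). With both sets the cholesterol (1.76e-05), NF-kB (0.0018), luminal progenitor (0.00211) and interferon (5.03e-12) lists differed in the same directions. In HCC70 against set b, VSNL1 was at -0.515 and ETV1 at 1.07.

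Against scrambled set b, EED knockdown in HCC70 lowered cholesterol synthesis, interferon and lineage marker genes and raised KIT. EED fell by 0.82 ± 0.105 on the log2 scale, 1.77-fold (adjusted p = 0.000347). EZH2 changed by -0.24 ± 0.07 (adjusted p = 0.0456), a call that ended without any 1 of the 4 arrays. The EZH2 change then lay between -0.26 and -0.214. KIT rose by 1.36 ± 0.13, 2.57-fold (adjusted p = 3.57e-05), KRT14 fell by 0.56 ± 0.09 (adjusted p = 0.00125) and KRT8 by 0.53 ± 0.09 (adjusted p = 0.00272). ALDH1A3 fell by 0.40 ± 0.07 (adjusted p = 0.00298). KRT5 changed by -0.28 (adjusted p = 0.0267), a call that also ended without any 1 of the 4 arrays. The KRT5 change then lay between -0.327 and -0.237. GATA3 changed by -0.32 (0.168), KRT18 by -0.17 (0.286), EGFR by -0.13 (0.537) and CDKN2A by -0.07 (0.61). Falls included the transcription cofactor gene VGLL1 (-3.05 ± 0.125, 8.26-fold), CCL2 (-3.04 ± 0.14), the aldehyde dehydrogenase gene ALDH1A1 (-2.89 ± 0.08, 7.40-fold, adjusted p = 3.99e-09), ELAPOR1 (-2.875 ± 0.20), the amino acid transporter gene SLC6A14 (-2.80) and KRT4 (-2.745). ELAPOR1 ended below the floor (4.865). The largest rise was in the metallothionein gene MT1M (3.045 ± 0.15, 8.25-fold).

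Of 19 cholesterol synthesis genes 0 rose and 17 fell (0 and 18 adjusted over the list alone), with TM7SF2 at -1.33 ± 0.105, DHCR7 at -1.09 ± 0.09 and the squalene epoxidase gene SQLE at -1.08 ± 0.10. The median change of the list was -1.002 (camera adjusted p = 6.75e-17, and adjusted p = 0.0111 with an estimated correlation). Interferon response genes had 0 of 35 higher and 22 lower (1 and 26 adjusted over the list alone, camera adjusted p = 3.02e-12, and adjusted p = 0.0201 with an estimated correlation), with SAMD9 at -1.05 ± 0.11 and MX1 at -0.745. Of 26 cytokine and NF-kB target genes 1 rose and 10 fell (1 and 14 adjusted over the list alone, camera adjusted p = 5.55e-07, and adjusted p = 0.0201 with an estimated correlation), including SAA2 (-2.30 ± 0.12) and CCL2. The 3 luminal and basal lineage lists shifted down. Luminal progenitor markers had 1 of 16 higher and 9 lower (1 and 11 adjusted over the list alone), with CD14 at -1.18 (camera adjusted p = 2.74e-06, and adjusted p = 0.0136 with an estimated correlation). Basal and myoepithelial markers had 0 of 18 higher and 8 lower, also adjusted over the list alone (camera adjusted p = 3.7e-06, and adjusted p = 0.0111 with an estimated correlation). The chaperone gene CRYAB (-2.14 ± 0.145), SNAI2 (-1.53) and DSG3 (-1.125) were among them. Mature luminal markers had 1 of 15 higher and 8 lower (1 and 9 adjusted over the list alone), with AGR2 at -1.07 and CA12 at -0.85 (camera adjusted p = 0.0002, and adjusted p = 0.0413 with an estimated correlation). Genes described as Polycomb targets had 1 of 19 higher and 6 lower (1 and 8 adjusted over the list alone, camera adjusted p = 0.000983, and adjusted p = 0.0201 with an estimated correlation). BMPR1B (-0.87), WNT5A (-0.80) and TIMP3 (-0.77) fell, with another TIMP3 cluster of the opposite sign. CRYAB, CA12 and WNT5A ended below the floor, and BMPR1B was below it in both groups. Epithelial junction genes had 0 of 23 higher and 4 lower (0 and 6 adjusted over the list alone, camera adjusted p = 0.00846, and adjusted p = 0.286 with an estimated correlation).

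Cell cycle genes shifted up, with 13 of 40 higher and 2 lower (18 and 4 adjusted over the list alone, camera adjusted p = 0.000419, and adjusted p = 0.169 with an estimated correlation). CDC25C (0.62 ± 0.08) and the mitotic kinase gene AURKA (0.715 ± 0.115) were among them. Of 26 genes of the unfolded protein and amino acid response 9 rose and 1 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.0303, and adjusted p = 0.298 with an estimated correlation), with the cystine transporter gene SLC7A11 at 1.00 ± 0.10. The other 8 lists had camera adjusted p from 0.0535 to 0.878. Mesenchymal markers had 0 of 16 higher and 4 lower (0 and 4 adjusted over the list alone, 0.0535). In the same order, antigen presentation genes had 3 of 14 and 1 (3 and 2, 0.875), with a median of -0.13 and a mean of 0.05. For p53 targets the counts were 4 of 21 and 1 (4 and 3, 0.221), and for hypoxia genes 4 of 26 and 2 (5 and 3, 0.429). PRC2 subunits had 0 of 12 and 2 (2 and 4, 0.429) and PRC1 subunits 0 of 15 and 1 (0 and 1, 0.668). HOX genes had 1 of 12 and 1 (1 and 1, 0.878) and markers of other cell types 0 of 3 and 0 (0 and 0, 0.878).

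In all, 2290 clusters passed the threshold, 1072 higher and 1218 lower, of which 43 and 163 changed at least 2-fold. The count was 1013 and 1047 without set b replicates 1 and 2, 1128 and 1062 without shEED replicates 1 and 2, and 4439 from the 4 arrays alone. Against set a, with the same shEED arrays and so not independently, 1558 of the 2290 calls were made again in the same direction and 79 in the opposite one. The cholesterol (camera adjusted p = 3.8e-05), basal (1.71e-05), mature luminal (0.000578) and cell cycle (0.018) lists stayed past the threshold. The interferon (0.97), NF-kB (0.349), luminal progenitor (0.597), Polycomb target (0.18), junction (0.97) and unfolded protein (0.268) lists did not. MX1 (0.47, adjusted p = 0.00295) and ALDH1A3 (0.56, adjusted p = 0.000125) were past it with the sign turned. EZH2 changed by -0.17 (adjusted p = 0.0785) and GATA3 by -0.49 (0.0192). EED, KIT, KRT14 and KRT8 were past the threshold in the same direction. The p53 target list was past it, shifted up (camera adjusted p = 0.0432). Of 42 named genes called against set b, 19 moved by over 1.5 times or changed sign. CCL2 was at -1.11, ELAPOR1 at -0.93, SLC6A14 at -1.22, SAA2 at -0.855, SNAI2 at -0.99, DHCR7 at -0.585, SQLE at -0.71 and TIMP3 at -0.33. KIT (2.145), SLC7A11 (1.915), KRT14 (-1.30) and KRT5 (-0.545) changed more.

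**Figure D2:**
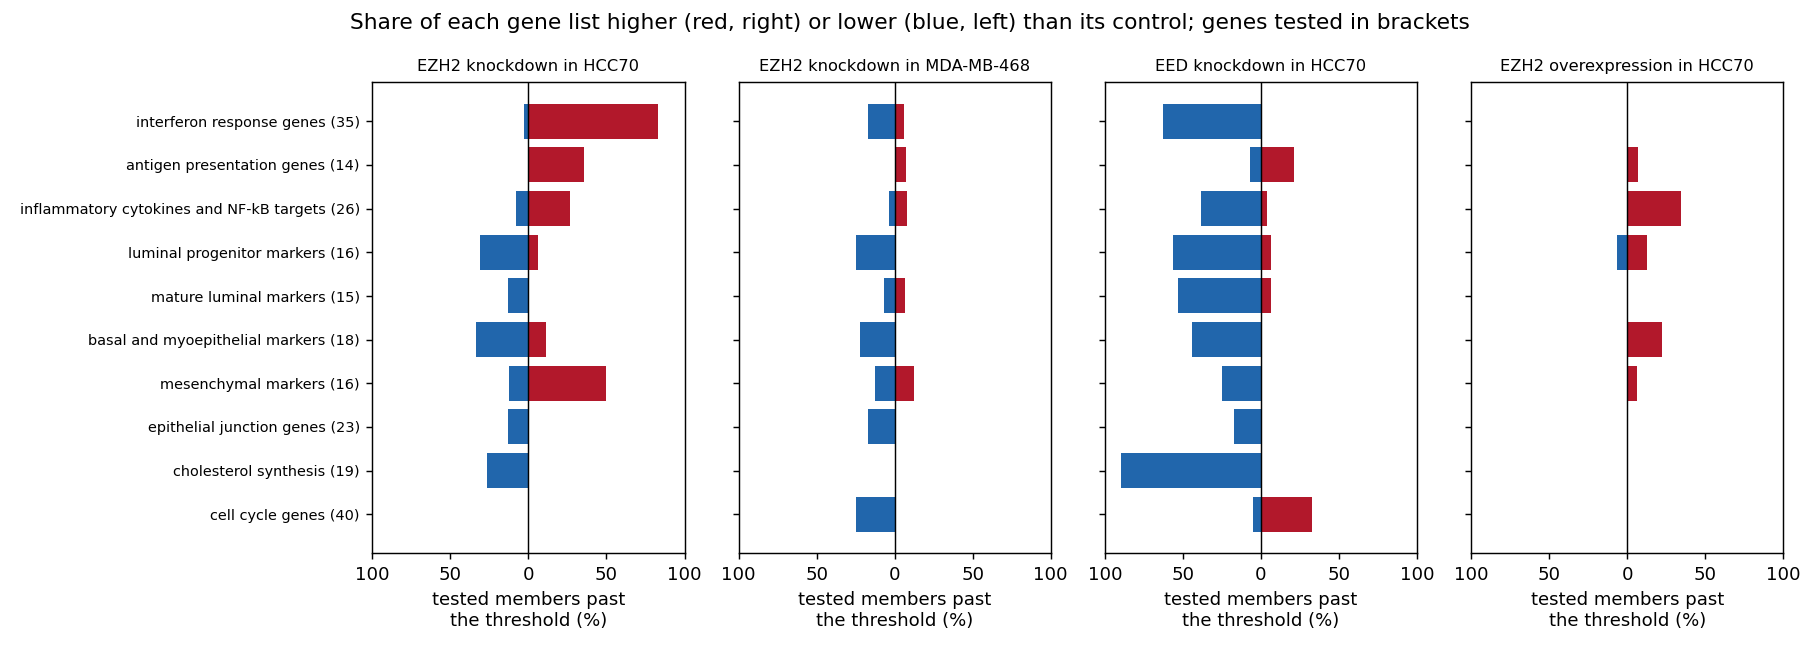
Percent of the tested members of 10 gene lists called higher (red, right) or lower (blue, left) in each of the 4 comparisons at an adjusted p under 0.05. Of 35 interferon response genes 29 were higher with EZH2 knockdown and 22 lower with EED knockdown in HCC70, and of 19 cholesterol synthesis genes 17 were lower with EED knockdown.

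The effects of EZH2 and EED knockdown in HCC70 differed in 1021 clusters, 704 with a higher change under EZH2 knockdown and 317 with a lower one. The changes correlated at r = 0.285 across clusters (0.237 to 0.297 leaving out 1 array). With both sets as control r was 0.15, but shared control arrays alone gave a mean r of 0.334 in simulations of unchanged groups. The covariance was 0.0158, against 0.0052 simulated. The simulated controls held no difference between sets a and b, unlike the measured ones, so the simulated values give no benchmark here. The r of 0.15 is thus no measure of agreement. In all 274 clusters rose in both (78.3 for independent lists), 278 fell in both (49.4) and 127 were called in opposite directions. Of these, 105 were higher with EZH2 and lower with EED knockdown (88.9 for independent lists) and 22 the reverse (43.5). KRT4 (-2.36 and -2.745), MMP7 (-2.32 and -2.17), SLC6A14 (-1.91 and -2.80) and CALB1 (-3.68 and -1.53) fell with both. The ion channel gene TRPC1 (1.59 and 1.52) and MT1M (1.39 and 3.045) rose with both. CALB1 ended below the floor with both, and TRPC1 was below it in set a, set b and the shEZH2 arrays. By the contrast of the effects (EZH2 minus EED), CCL2 (4.74 ± 0.20, adjusted p = 6.09e-07), LTF (2.96 ± 0.32), IFIT1 (2.845), C1S (2.73) and PLXDC2 (2.60) changed more upward with EZH2 knockdown. KIT (-3.105 ± 0.18, adjusted p = 3.5e-06), the Notch target gene HEY2 (-2.95 ± 0.16), PLA2G2A (-2.87), CALB1 (-2.15) and AKR1C2 (-2.04) changed more downward. The shEZH2 means of these 5 genes were below the floor. The interferon list differed (27 of 35 higher and 0 lower, camera adjusted p = 7e-35, and adjusted p = 0.00431 with an estimated correlation). So did the cholesterol list (12 of 19 higher and 0 lower, camera adjusted p = 1.53e-09, and adjusted p = 0.0259 with an estimated correlation). The NF-kB (11 of 26 higher and 0 lower, camera adjusted p = 2.41e-09, and adjusted p = 0.0231 with an estimated correlation), mesenchymal (7 of 16 and 0, 2.53e-05 and 0.0259) and Polycomb target (4 of 19 and 0, 0.001 and 0.0259) lists also changed more upward with EZH2 knockdown. With an estimated correlation 6 further lists were not past the threshold. Of these, mature luminal (camera adjusted p = 0.00801, and adjusted p = 0.114 with an estimated correlation), luminal progenitor (0.0182 and 0.114), antigen presentation (0.001 and 0.114) and basal (0.0462 and 0.114) genes changed more upward. Cell cycle genes (0.000495 and 0.131) and the unfolded protein response (0.00931 and 0.222) changed more downward. The camera adjusted p of the basal list was 0.0556 without set a replicate 1, 0.166 without shEZH2 replicate 2, 0.0588 without set b replicate 1 and 0.0874 without shEED replicate 2. KRT8 differed by 0.71 (adjusted p = 0.00749) and KRT14 by -0.26 (adjusted p = 0.254). The count was 598 and 516 without set a replicates 1 and 2, 461 and 494 without set b replicates 1 and 2, and 506 and 553 without shEED replicates 1 and 2. Exchanging the sets adds set a minus set b to the EZH2 change and subtracts it from the EED change. As shEZH2 minus shEED correlated with set a minus set b (r = 0.568), r then falls by construction. The values with exchanged sets thus largely restate the set difference and are no separate evidence on agreement. With the sets exchanged r was -0.328, and LTF (-2.22) and CALB1 (2.56) differed the other way. The difference was 0.89 for CCL2, 0.57 for IFIT1, 1.47 for C1S, 1.28 for PLXDC2, -3.58 for AKR1C2, -4.67 for KIT and -3.065 for HEY2. The interferon (camera adjusted p = 0.0194), mature luminal (0.0138) and basal (0.013) lists differed in the same direction, and the NF-kB (0.015) and luminal progenitor (0.00461) lists in the opposite one. The cholesterol (0.259), mesenchymal (0.531), Polycomb target (0.18), antigen presentation (0.259), cell cycle (0.0646) and unfolded protein (0.259) lists did not pass the threshold. With the sets exchanged TRPC1 changed by 0.67 and 2.44, SLC6A14 by -3.50 and -1.22 and CALB1 by -1.32 and -3.88 with EZH2 and EED knockdown. MT1M changed by 0.515 with EZH2 knockdown.

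With EZH2 overexpression in HCC70 the cytokine and NF-kB target list shifted up and KIT fell. EZH2 signal was 0.29 ± 0.07 higher, 1.23-fold, with an adjusted p of 0.0961 that did not pass the threshold, and EED changed by -0.03 (adjusted p = 0.948). The cytokine gene LIF rose by 1.60 ± 0.14 (3.03-fold, adjusted p = 0.000555), the kallikrein protease genes KLK10 and KLK6 by 1.36 ± 0.095 (adjusted p = 0.000138) and 1.16 ± 0.11, the acute phase gene SAA2 by 1.21 ± 0.12 and the cornified envelope gene SPRR2A by 1.23 ± 0.13 from below the floor. KIT fell by 1.24 ± 0.13, 2.355-fold (adjusted p = 0.00156). KRT14 changed by 0.50 ± 0.09 (adjusted p = 0.0212). That call ended without any 1 array, with the change then between 0.473 and 0.534. GATA3 (0.09, adjusted p = 0.902), KRT5 (0.10, 0.724), KRT8 (0.175, 0.57), KRT18 (0.08, 0.859), ALDH1A3 (0.17, 0.412), EGFR (0.16, 0.71) and CDKN2A (0.03, 0.942) were not past the threshold.

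Of 26 cytokine and NF-kB target genes 9 rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 1.95e-14, and adjusted p = 0.00496 with an estimated correlation). The chemokine gene CXCL8 was among them at 1.28 ± 0.18 (adjusted p = 0.00565), a call that ended without cDNA replicate 2 (then 1.178). Of 18 basal and myoepithelial markers 4 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 5.27e-08, and adjusted p = 0.00419 with an estimated correlation). The actin-binding gene TAGLN was at 0.96 ± 0.14 (adjusted p = 0.00905). That call ended without vector replicate 1 (then 0.955) or either cDNA replicate (then 1.014 and 0.9). Among 21 p53 targets 1 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.00642, and adjusted p = 0.059 with an estimated correlation). The camera adjusted p was 0.0982 without vector replicate 2 and 0.141 without cDNA replicate 2. The other 15 lists had camera adjusted p from 0.15 to 0.99. Luminal progenitor markers had 2 of 16 higher and 1 lower (5 and 2 adjusted over the list alone, 0.15), with KRT15 at 0.93 ± 0.07. In the same order, epithelial junction genes had 0 of 23 and 0 (2 and 0, 0.15) and cell cycle genes 0 of 40 and 0 (0 and 1, 0.15). PRC1 subunits had 1 of 15 and 0 (3 and 0, 0.245), Polycomb targets 1 of 19 and 0 (1 and 0, 0.245) and antigen presentation genes 1 of 14 and 0 (1 and 0, 0.245). Mesenchymal markers had 1 of 16 and 0 (1 and 0, 0.99), the unfolded protein response 1 of 26 and 0 (3 and 0, 0.99) and hypoxia genes 1 of 26 and 0 (2 and 0, 0.927). PRC2 subunits (0.927), mature luminal markers (0.927), HOX genes (0.927), interferon response genes (0.927), cholesterol synthesis (0.816) and markers of other cell types (0.816) had no member called over all genes. The median, mean and test differed in sign for PRC2 subunits and the mesenchymal, interferon, hypoxia and cholesterol lists.

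In all, 158 clusters passed the threshold, 147 higher and 11 lower, of which 15 and 1 changed at least 2-fold. The count was 51 and 97 without vector replicates 1 and 2, 39 and 14 without cDNA replicates 1 and 2, and 0 from the 4 arrays alone, where limma gave 1405 clusters with an unadjusted p under 0.05.

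**Figure D3:**
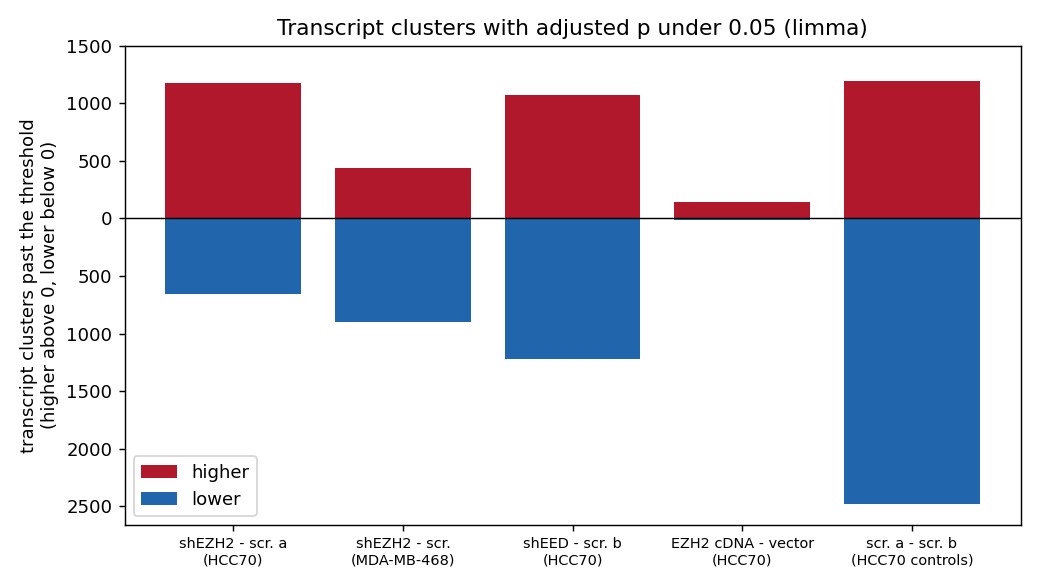
Number of clusters (vertical axis) called higher and lower at an adjusted p under 0.05 in the 4 comparisons and between the scrambled sets a and b of HCC70. The comparison of the control sets called 3677 clusters and EZH2 overexpression 158.

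Knockdown and overexpression of EZH2 in HCC70 were set against each other for opposite changes. The changes correlated at r = -0.05 across clusters, and between -0.099 and 0.002 leaving out 1 array. Of the clusters called in both, 45 went opposite ways, 42 of them lower with knockdown and higher with overexpression (5.96 for independent lists) and 3 the reverse (0.803). The other 33 went the same way, 28 of them higher with both (10.7 for independent lists) and 5 lower (0.446). Here too the overlaps lay above the counts for independent lists whichever the direction. CRYAB (-1.07 and 0.91) and SLC6A14 (-1.91 and 0.90) fell with knockdown and rose with overexpression. KIT fell with both (-1.74 and -1.24). SPRR2A (1.21 and 1.23), CCL2 (1.70 and 1.01) and the cytokine gene IL6 (0.83 and 0.785) rose with both. IL6 was below the floor in set a and the shEZH2 arrays. Several overexpression calls ended when 1 array was left out, which also lowers precision. Those of CRYAB, CCL2 and IL6 ended without vector replicate 1 or either cDNA replicate, and that of SLC6A14 without any 1 array. The changes then lay between 0.719 and 0.952 for CRYAB and between 0.853 and 0.944 for SLC6A14. They lay between 0.95 and 1.071 for CCL2 and between 0.66 and 0.838 for IL6. Against set b the knockdown changes of CCL2 (-0.225) and IL6 (-1.47) were below 0, those of SLC6A14 (-3.50) and SPRR2A (4.12) were larger, and r was -0.196 (-0.153 with both sets).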

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

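All tests of explanations in this part were chosen after the results were seen. The effect of EZH2 knockdown differed between HCC70 and MDA-MB-468 by the limma interaction contrast in 2141 clusters and in the interferon response list (camera adjusted p = 8.58e-17). The change was higher in HCC70 by 3.43 log2 units for FN1, 3.22 for IGFBP5, 2.85 for the small nucleolar RNA SNORD41, 2.535 for LTF and 2.53 for C1S. The HCC70 change minus the MDA-MB-468 change was -2.25 for SLC6A14, -2.30 for AKR1C2, -2.43 for MMP7, -2.60 for PLA2G2A and -3.53 for CALB1. In the lineage panel it was -0.79 for KRT14 and -1.75 for KIT. KIT (4.10 in scrambled and 4.11 in shEZH2 arrays) and CALB1 (4.30 and 4.15) lay below the floor of log2 6 in both MDA-MB-468 groups, so a fall there could not show and their differences give no evidence of a line-specific effect. LTF and C1S lay below it there as well, IGFBP5 in the MDA-MB-468 shEZH2 arrays, SNORD41 in set a and AKR1C2 in the HCC70 shEZH2 arrays. PLA2G2A ended below the floor in both lines (5.68 and 5.52), which limits the size of its fall in MDA-MB-468. Against scrambled set b the differences of LTF (-0.05, adjusted p = 0.933) and KRT14 (-0.05, adjusted p = 0.823) were not past the threshold, and the other 8 genes, leaving KIT and CALB1 aside, were past it with the same sign. FN1 was then at 1.54, CALB1 at -1.17 and SLC6A14 at -3.83.

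Interferon response genes rose with EZH2 knockdown in HCC70, by a median of 0.77 log2 units against set a. A low level of these genes in set a alone is argued against as the whole cause, since against set b the median was 0.33 with the list still past the threshold (camera adjusted p = 1.12e-05), though the smaller median leaves room for a part of it. A single outlying array is also argued against, because at least 23 of the 35 genes stayed called higher whichever array was left out. Loss of the shared complex would raise the list with EED knockdown too; against the same set a its median there was 0.06 (camera adjusted p = 0.97), and against set b the list fell, but the EED transcript fell less than EZH2 did, so an effect that needs a deeper loss stays open. An off-target or infection response of the shEZH2 culture stays open as well, as only 1 shRNA group per gene was analysed here, and the shift was not past the threshold in MDA-MB-468.

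KIT fell with EZH2 knockdown, rose with EED knockdown and fell with EZH2 overexpression in HCC70. If the level of the control cultures accounted for this, treated arrays would lie within the range of the 6 HCC70 control arrays (6.26 to 7.64). Both shEZH2 arrays lay below that range by at least 1.51, more than the width of the range (1.382), which argues against this explanation for the fall with EZH2 knockdown, though the range comes from 3 control groups only. Both shEED arrays lay above the range by at least 0.73, less than its width, so variation in KIT between cultures stays open for the rise with EED knockdown. With EZH2 overexpression the higher array lay inside the range (-0.23 for the lowest control minus the highest treated array), so a control culture with high KIT may account for that fall. Opposite effects of the subunits on KIT remain a hypothesis, and shRNA off-target effects and differences between the cultures were not tested.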

How the results depend on the processing

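Stricter thresholds and leaving out single arrays each moved all 6 counts of called clusters by over 1.5 times, array weights moved 5, the 4 arrays alone moved all 4 they could give, and another scrambled set moved 3 of 4. Leaving out both arrays farthest from their duplicate (shEZH2 replicate 2 and vector replicate 1 of HCC70) and testing 1 cluster per symbol were chosen after seeing the data. Where an array was left out, the lone sample was assumed to vary like the other groups. Stricter thresholds call fewer clusters by construction, and leaving out 1 array of a pair raises the standard error of that comparison. A call that ends without an array thus need not depend on that array. The cause of each change was otherwise not tested. A floor of log2 7, quantile normalization once more, a mean-variance trend, a robust prior and 1 cluster per symbol kept every count within 1.5 times. Dim clusters near the floor have little signal over background.

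Counts are given in the order EZH2 knockdown in HCC70, EZH2 knockdown in MDA-MB-468, EED knockdown, EZH2 overexpression, difference between lines, difference between EZH2 and EED knockdown. At an adjusted p under 0.01 they were 735, 322, 1145, 52, 652 and 426, and with a 2-fold minimum 181, 51, 206, 16, 375 and 253. Array weights gave 1021, 418, 5935, 72 and 979 for the first 5. The 4 arrays alone gave 276, 21, 4439 and 0 for the first 4 (limma gave 3148, 2800, 6793 and 1405 at an unadjusted p under 0.05). Without a filter MDA-MB-468 had 848 and overexpression 88, and with median centring overexpression had 88 and the difference between subunits 677. Without both far arrays MDA-MB-468 had 2245, overexpression 74, the difference between lines 3213 and that between subunits 1821. Leaving out 1 array, the counts ranged from 688 to 1977, 231 to 1552, 1013 to 1128, 14 to 97, 921 to 2633 and 461 to 1522.

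With the other scrambled set EZH2 knockdown in HCC70 had 4325 clusters, EED knockdown 5940 and their difference 6843. With both sets EZH2 knockdown had 3048 clusters and EED knockdown 4465. The control arrays then cancel out of their difference, so its 5169 clusters compare shEZH2 with shEED arrays directly. Any difference between the 2 experiments is left in that count. The EZH2 against EED correlation was -0.328 with the other set and 0.15 with both (range 0.237 to 0.297 leaving out 1 array). With the other set, the set difference enters the 2 changes with opposite signs, so that r and the count of 6843 largely restate it. With both sets the controls are shared: 100 simulations of unchanged groups gave a mean r of 0.334 and covariance of 0.0052, against an observed r of 0.15 and covariance of 0.0158. These simulations held no difference between sets a and b, so they give no benchmark for the measured data. The correlation between lines was 0.104, 0.005 and, with 1-symbol clusters only, -0.025 (-0.161 to -0.058 leaving out 1 array), and that of knockdown with overexpression -0.196 and -0.153 (-0.099 to 0.002). With the other set ALDH1A3 changed by -0.94 (adjusted p = 3.23e-06), LTF by -0.02 (0.958), VIM by -0.167 (0.209), CCL2 by -0.225 (0.27) and IL6 by -1.468 (6.42e-06) with EZH2 knockdown. With EED knockdown ALDH1A3 changed by 0.557 (adjusted p = 0.000125), MX1 by 0.472 (0.00295), IFIT1 by 0.167 (0.365), PLXDC2 by 0.082 (0.509), LTF by 2.198 (2.81e-05) and AKR1C2 by 0.211 (0.313). With both sets ALDH1A3 changed by -0.462 (adjusted p = 0.000362) with EZH2 and 0.079 (0.367) with EED knockdown, IL6 by -0.319 (0.0523) with EZH2 knockdown and LTF by 0.904 (0.0052) with EED knockdown.

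For gene lists, the estimated correlation left 1 list with EZH2 knockdown in HCC70, 0 in MDA-MB-468, 7 with EED knockdown and 2 with overexpression, in the same test against other genes. By fry, which tests lists against no change and answers another question, 12, 6, 13 and 5 lists passed. MDA-MB-468 had 4 lists without a filter, and EED knockdown 5 with the other set. Leaving out 1 array gave 4 to 8, 0 to 4, 10 to 11 and 2 to 3 lists.

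Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at 0.0774, -0.0228, -0.00199 and 0.00225 in the 4 comparisons. With the number as a replicate block EZH2 knockdown in MDA-MB-468 had 679 clusters and 3 lists, and overexpression 39 clusters. The other counts stayed within 1.5 times.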

Other observations

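The tests of the r between the knockdown arrays and the control sets were chosen after the result was seen, as were the metallothionein genes, the relation of EED knockdown with overexpression and the share of dim clusters in the treatment comparisons. The other tests of explanations here were chosen before, except the draws of sets matched on mean level, for which no earlier choice is on record. Metallothionein genes code for small metal-binding proteins, and no enrichment test was run on them. Of 12 tested, 7 rose with EZH2 knockdown in HCC70, 7 in MDA-MB-468 and 9 with EED knockdown, and 0 fell. The median changes were 0.43, 0.43 and 0.60. With EZH2 overexpression 0 passed the limma threshold (4 at an unadjusted p under 0.05), all 12 changes were below 0 and the median was -0.23. With median centring 5, 5 and 7 rose, and with the other scrambled set 4 rose with EZH2 and 12 with EED knockdown in HCC70. With that set the median for EZH2 knockdown was 0.208, with 10 of 12 changes above 0. The genes are near-identical copies, so cross-hybridisation between their clusters was not excluded.

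With set b as the EED control, many clusters called with both EED knockdown and EZH2 overexpression in HCC70 differed in opposite directions. Of the clusters called in both, 93 went opposite ways, 88 of them lower with EED knockdown and higher with overexpression (11.1 for independent lists) and 5 the reverse (0.729). Another 6 went the same way, 4 higher (9.74) and 2 lower (0.828). The protease genes KLK10 (-1.87 and 1.36) and KLK6 (-1.20 and 1.16), SAA2 (-2.30 and 1.21) and KIT (1.36 and -1.24) were among those that went opposite ways. KLK6 ended below the floor of log2 6 with EED knockdown. With set a as the EED control SAA2 changed by -0.855 and KIT by 2.145. Across clusters r was -0.333, between -0.390 and -0.147 leaving out 1 array, -0.0909 with set a as the EED control and -0.211 with both sets. Of the clusters higher with overexpression 101 differed between sets a and b, 80 of them lower in set a. A high level in set b would also give a fall with EED knockdown, so the choice of control may carry part of the opposition. The overlap with set a as the EED control was not counted.

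The scrambled sets a and b of HCC70 differed in 3677 clusters, with 1198 higher and 2479 lower in set a. The interferon list (0 of 35 higher and 22 lower, camera adjusted p = 1.2e-08) and the NF-kB list (0 of 26 and 17, camera adjusted p = 1.2e-08) were lower in set a. With an estimated correlation the interferon list was not past the threshold (adjusted p = 0.0981) and the NF-kB list was (adjusted p = 0.0276). Luminal progenitor markers (1 of 16 higher and 12 lower, camera adjusted p = 7.2e-06, and adjusted p = 0.0276 with an estimated correlation) and cholesterol synthesis (0 of 19 and 13, 2.37e-05 and 0.123) were also lower in set a, and HOX genes higher (4 of 12 and 1, 0.0274 and 0.102). After quantile normalization once more 3288 of the calls stayed. RMA had already normalized between arrays, so a repeat could change little and does not decide whether scaling plays a part. An array-wide difference in hybridisation stays open. Of the dim clusters 10.35% had an unadjusted p under 0.05, against 36.5% of the tested ones, but dim clusters show less of any difference. Their share was also under 0.5 times that of the tested clusters in each treatment comparison (0.195 to 0.462 times). A difference shared with the knockdown arrays of the same experiment is consistent with the r of 0.568 between shEZH2 minus shEED and set a minus set b. Culture state and the time of the experiment are not given in the sources used here, so the source of that difference stays open.

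A hypothesis is that genes higher with EZH2 overexpression are largely genes that vary between HCC70 control cultures. Of the clusters higher with overexpression, 68.7% differed between sets a and b, against 22.7% of all tested clusters. Drawing 1000 sets matched on mean level gave a median of 23.1% and at most 38.1%. The draws were not matched on the spread between duplicates, which bears on calls in both comparisons, so called clusters can exceed them for that reason. Of the 101 that differed, 80 were lower and 21 higher in set a. The share was 35.2% among the calls of EZH2 knockdown in MDA-MB-468, which has no array in common with sets a and b. The result is in line with the hypothesis and does not exclude an effect of EZH2, whose transcript was 1.23-fold higher (adjusted p = 0.0961).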
